A study of Mus musculus with 9 samples.

How the data were processed

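The labels describe total RNA of fetal thymic lobes at day e13.5 from C57BL/6 mice of 3 genotypes, with 3 arrays each. It was amplified and biotin-labelled with Affymetrix whole-transcriptome kits and hybridised to Clariom S mouse arrays. The deposited log2 values of the series were used as given. They ran from 1.47 to 19.92, a range that log2 values fit and linear intensities do not. The software and its version, the normalization method and the genome build are not given in the sources used here. The column medians lay within 5.09 to 5.20 but were not equal. The series held 28846 features, of which 6640 control features were left out (5222 negative controls, 1324 positive controls, 23 background probes and 71 others), leaving 22206 transcript clusters. Of these, 19572 had 1 gene symbol (19505 distinct symbols, all matched in a RefSeq gene annotation of assembly GRCm38.p6, which was used for names and gene neighbours only) and 2634 had none. The values of 142 clusters repeated those of another cluster on all arrays.

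Groups followed the genotype in the labels. The sample titles carry 3 date codes, called A, B and C here: code A holds wild type replicate 3, Foxn1 mutant replicate 2 and Tbx1 mutant replicate 1, code B wild type replicate 2 and Foxn1 mutant replicates 1 and 3, and code C wild type replicate 1 and Tbx1 mutant replicates 2 and 3. What the codes stand for is not given in the sources used here. The 7 pairs of arrays that share a code and differ in genotype had a mean correlation of deviations of 0.025 (-0.39 to 0.32), and the 20 pairs that share neither had -0.003.

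A linear model with a term for each genotype was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table), with empirical Bayes moderation and two-sided tests. Foxn1 mutants and Tbx1 mutants were each compared with wild type and with each other, and a moderated F test asked for any difference. P-values were adjusted by Benjamini and Hochberg over the 22206 clusters in each comparison, with a threshold of 0.05. Errors given with ± are SDs over the 3 arrays or SEs from the model, as stated. Gene lists for thymic epithelium, leukocytes, other tissues of the neck and chest, stress, signalling and the neighbours of both targeted genes, 40 in all, were fixed before the data were examined. The 37 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and adjusted over 37. Camera with a correlation estimated for each list and fry served as alternatives. Fry asks whether a list moves on balance in 1 direction or, in its mixed form, in either, and does not compare it with other genes. Members were also adjusted over the list alone. A gene with several clusters was represented by the one with the highest mean.

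The rule for named genes was fixed before the data were examined. It took the targeted genes, up to 10 called genes per direction whose arrays do not overlap, a fill to 5 per direction by lowest p, given as values, and up to 4 members of lowest p of each list that was called or held a called gene. Other genes named were chosen after their values were seen: Prss16, Psmb11, Ptprc and Myl7, the gene Kdm5d, and those of the closing observations.

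The fit was tested on simulated data in 10 runs with 200 changed clusters of 22206 each. For Foxn1 mutants against wild type it recovered 21.2% of changes of 1 log2 unit, 73.4% of changes of 2, 93.6% of changes of 4 and 97.6% of changes of 6, with 4.98% false among the calls. For Tbx1 mutants against wild type the shares were 20.2%, 75.6%, 94.2% and 98.2%, with 4.07% false. In each run the T lineage list was also raised by 2 log2 units, and noise was drawn independently for each cluster. The real arrays held structure shared across clusters, and few changed clusters make the adjusted threshold stricter. These shares are therefore not the power in the real data. The simulated correlations with arrays left out, and the estimated correlation in fits with a date code block or fewer arrays, were added after the data had been seen, as was the bound that puts each array's negative-control median in place of lower values.

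Alternatives fixed before the data were examined were quantile normalization, median centring, leaving out clusters with a mean under 3.44 or under 5.15 (16654 and 11103 left), an intensity trend with robust moderation, array weights, the date code as a fixed or a random block, other thresholds, only the arrays of the groups compared, and leaving out each array in turn. In the last, a genotype with fewer arrays is assumed to vary like the others. Chosen after seeing the data were leaving out wild type replicate 1 and Foxn1 mutant replicate 2 together, leaving out X and Y clusters (21011 left), a term for sex read from Uty and Kdm5d, and keeping 1 cluster of each identical set (22064 left). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.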

Results

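Total RNA from fetal thymic lobes of C57BL/6 mice at day e13.5 was measured on 9 whole-transcriptome Clariom S arrays. There were 3 arrays of wild type, 3 of Foxn1933/1089 and 3 of Tbx1neo2/neo2. Foxn1 encodes the transcription factor that thymic epithelial cells need to differentiate, and the Foxn1933/1089 mice carried a different mutant allele on each chromosome (here, Foxn1 mutants). Tbx1 encodes a T-box factor that patterns the pharyngeal pouches, from which thymus and parathyroid arise, and neo2 is an allele known to lower its expression (here, Tbx1 mutants). The labels do not say that the samples of a genotype came from separate embryos, so the p-values measure only the spread between these samples. The array medians lay between 5.09 and 5.20 on the log2 scale, the medians of the negative-control probes between 4.27 and 4.94, and the number of arrays limits the precision.

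Most arrays carried a strong thymic signature. Prss16, a protease of cortical thymic epithelium, read between 13.87 and 14.43 on 7 of the arrays, and Psmb11, the thymus-specific proteasome subunit, between 9.52 and 10.66. On wild type replicate 1 and Foxn1 mutant replicate 2 these genes stood near background, with Prss16 at 4.24 and 4.45 and Psmb11 at 3.40 and 3.36. The mean log2 difference from the other 7 arrays was -2.94 and -2.99 for the leukocyte list and -2.67 and -2.46 for the FOXN1-dependent epithelial genes. Wild type replicate 1 had high neuronal genes, with Th, the enzyme that starts catecholamine synthesis, at 12.44 (2.56 to 4.07 elsewhere). Foxn1 mutant replicate 2 had the highest Myl7, an atrial myosin light chain, at 10.71 (3.55 to 6.54 elsewhere). The first principal component held 42.6% of the variance and set these 2 arrays (scores -109 and -57.4) against the others (7.69 to 38.3).

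**Figure D1:**
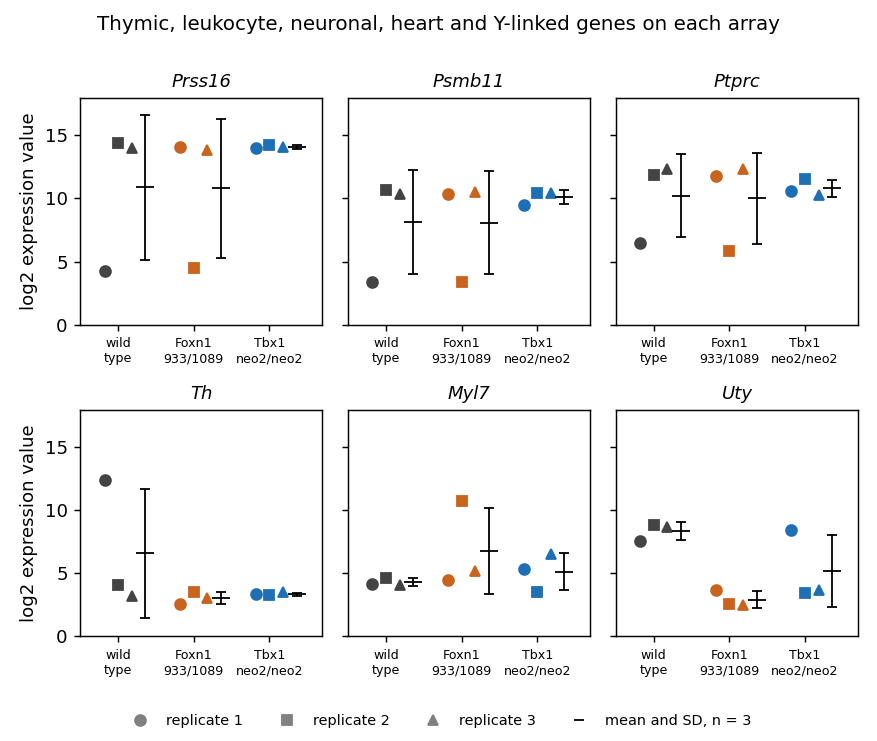
Log2 values of Prss16, Psmb11, Ptprc, Th, Myl7 and Uty on each of the 9 arrays, with points for single arrays and bars for the mean and SD of each genotype (n = 3). Prss16 stands at 4.24 on wild type replicate 1 and 4.45 on Foxn1 mutant replicate 2, and between 13.87 and 14.43 on the others.

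The targeted genes did not separate the genotypes. Foxn1 read 7.78, 10.35 and 10.01 on the 3 wild type arrays, 9.02, 8.73 and 9.67 on the Foxn1 mutants, and 8.88, 10.04 and 9.70 on the Tbx1 mutants. Its difference between Foxn1 mutants and wild type was -0.24 ± 0.62 (SE, n = 3 per genotype; adjusted p = 1.00). Within the date codes of the sample titles it was -1.28 (code A, a single array of each genotype) and -1.005 (code B, a single wild type array). The Tbx1 mutants differed from wild type in Foxn1 by -1.125 within code A and by 2.09 within code C, so the fall in code A was not particular to the Foxn1 mutants. The difference of Foxn1 between Foxn1 mutants and wild type was -1.04 without wild type replicate 1, 0.25 without replicate 2 and 0.08 without replicate 3. Tbx1 lay near the negative controls, at 5.85, 4.25 and 4.54 in wild type, 4.07, 4.83 and 4.61 in the Foxn1 mutants and 5.38, 4.80 and 5.30 in the Tbx1 mutants. The difference between Tbx1 mutants and wild type was 0.28 ± 0.41 (SE, n = 3 per genotype). The sources used here do not say whether the probes lie in the altered parts of these genes, so their levels do not check the genotypes.

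The comparison of Foxn1 mutants with wild type addresses how the transcriptome of the fetal thymus differs in compound heterozygous Foxn1 mutants. No single gene passed the test, but lists of matrix and mesenchyme genes were higher in the Foxn1 mutants and lists of erythroid, hypoxia, neuronal and muscle genes were lower, in calls that all ended with an estimated correlation. Dcn, the matrix proteoglycan decorin, read 16.13 ± 0.51 in the Foxn1 mutants against 14.59 ± 0.11 in wild type (SD, n = 3), and Col3a1, a fibrillar collagen, 11.87 ± 0.58 against 10.79 ± 0.30. The Y-linked gene Uty read 2.47 to 3.71 on the Foxn1 mutant arrays and 7.56 to 8.84 on the wild type arrays. The FOXN1-dependent genes as a list were not called.

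With limma, 0 of the 22206 transcript clusters passed an adjusted p of 0.05 between Foxn1 mutants and wild type (lowest adjusted p = 1.00). At an unadjusted p under 0.05 there were 898 clusters, 506 higher and 392 lower, where chance gives 1110. The 3 Foxn1 mutant arrays did not overlap the 3 wild type arrays at 8.29% of clusters, where chance gives 10%. The smallest exact p that 3 arrays against 3 can give for a single value is 0.1. The genes with the lowest p are given as values and not as changes. On the higher side they were Dcn (1.53 ± 0.27, SE), the X-linked neuronal membrane protein gene Slitrk4 (1.68 ± 0.31), Dcaf6 (1.26 ± 0.25), the olfactory receptor gene Olfr658 (1.31 ± 0.27) and Tbx18 (1.37 ± 0.29), a T-box gene of mesenchyme. On the lower side they were Uty (-5.43 ± 1.14), Gadd45a (-1.06 ± 0.23), which is induced by DNA damage and growth arrest, the actin-binding Coro1c (-1.50 ± 0.33), the ubiquitin ligase gene Mkrn1 (-1.11 ± 0.24) and Lrrc18 (-0.85 ± 0.19). Uty was under the negative-control medians on the Foxn1 mutants, so the size of its difference is limited there. Olfr658 and Lrrc18 read under the negative-control medians on all 9 arrays, so their differences are between background values. Without Tbx1 mutant replicate 1, 3 clusters were called lower in the Foxn1 mutants, among them Uty and the Y-linked Kdm5d.

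The camera set test called 6 of 37 lists between Foxn1 mutants and wild type; none of the 6 held with an estimated correlation (adjusted p = 0.971 for each), and fry in its directional form called 0. The extracellular matrix list rose (adjusted p = 5.21e-08; adjusted p = 0.971 with an estimated correlation), with 17 of 19 members higher and a median of 0.62. Adjusted over the list alone, 2 of its members, Dcn and Col3a1, passed. Other members included Lum at 0.99 and Col6a3 at 0.85. Its median was 0.80 with the date code as a block, 1.42 within date code A and 0.48 within code B. The list mean was highest on Foxn1 mutant replicate 2 (11.29 against 10.23 and 10.05 on the other Foxn1 mutants and 9.71 to 9.86 in wild type), and the median was 0.38 without that array (0.38 to 0.90 with any 1 array left out). Without the 2 arrays that stood apart it was 0.32 (adjusted p = 0.00832; adjusted p = 0.796 with an estimated correlation). The mesenchyme and neural crest list rose (adjusted p = 0.00573; adjusted p = 0.971 with an estimated correlation) with a median of 0.33 and 15 of 18 members higher, among them Alx1 at 0.83, Osr1 at 0.92 and Tcf21 at 0.78. With any 1 array left out Alx1 ranged from 0.52 to 1.095, Osr1 from 0.29 to 1.32 and Tcf21 from 0.28 to 1.24. Adjusted over the list alone, 1 member passed, Tbx18. The median was 0.46 with the date code as a block, 0.84 within code A and 0.23 within code B. This list was also highest on Foxn1 mutant replicate 2 (7.65; 6.59 to 7.25 elsewhere). Without that array its median was 0.19 (adjusted p = 0.627) and without wild type replicate 2 it was 0.27 (adjusted p = 0.169); without both arrays that stood apart the adjusted p was 0.718 with a median of -0.01 (these 2 were left out together only after the data had been seen).

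Among the lists that fell, the erythroid list (adjusted p = 0.00164; adjusted p = 0.971 with an estimated correlation) had 7 of 9 members lower and a median of -0.40. Alas2, the first enzyme of heme synthesis in red cells, was at -1.74 and passed when adjusted over the list alone, the only member of the list to do so. The embryonic globins Hba-x and Hbb-bh1 were at -2.03 and -2.12, and the red cell anion exchanger Slc4a1 at -2.06. With any 1 array left out these 3 genes ranged from -2.84 to -1.51, -3.55 to -1.20 and -3.20 to -1.45. Within code A they were at -1.82, -2.43 and -2.365, and within code B at -1.03, -0.02 and -0.25. The erythroid median was -0.46 with the date code as a block, -1.46 within code A and -0.21 within code B. The erythroid list mean was 10.401 and 10.70 on wild type replicates 1 and 3 and 8.75 to 9.70 on the other arrays, and without wild type replicate 3 its median was -0.43 (adjusted p = 0.165). With any 1 array left out the median lay between -0.76 and -0.34, and it was -1.88 without the clusters whose mean was under 5.15. The hypoxia and glycolysis list fell (adjusted p = 0.00164; adjusted p = 0.971 with an estimated correlation), with 11 of 12 members lower and a median of -0.37. Its members Egln3, an oxygen-sensing hydroxylase, and Adm, a hypoxia-induced peptide hormone, were at -2.33 and -1.89, Ndrg1 was at -1.24 and Ankrd37 at -0.88; 0 members passed when adjusted over the list alone. The hypoxia median was -0.48 with the date code as a block, -1.39 within code A and -0.31 within code B. The list mean was 10.06 on wild type replicate 3 and 8.62 to 9.45 on the other arrays. Its median was -0.12 without wild type replicate 3 (adjusted p = 0.228) and -0.44 without Foxn1 mutant replicate 2 (adjusted p = 0.101), and -0.66 to -0.12 with any 1 array left out.

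The neuron and glia list (adjusted p = 0.00164; adjusted p = 0.971 with an estimated correlation) fell with all 11 members lower and a median of -1.90, and it moved with a single array. Its mean was 10.36 on wild type replicate 1 and 5.15 to 5.82 on the others; Th was at -3.53, Dbh, which makes noradrenaline, at -3.19, the neurofilament gene Nefm at -2.56 and the neuronal RNA-binding gene Elavl4 at -1.90. Th and Dbh were under the negative-control medians on all Foxn1 mutants and above them in wild type on replicate 1 alone. Without wild type replicate 1 the neuronal median was -0.05 (adjusted p = 0.572), with the date code as a block it was -0.28 (adjusted p = 0.199), and within codes A and B it was 0.29 and -0.17. The skeletal muscle list (adjusted p = 0.00928; adjusted p = 0.971 with an estimated correlation) fell with all 15 members lower and a median of -0.61, and its mean was 8.04 on wild type replicate 2 and 4.47 to 5.95 elsewhere. Acta1, skeletal actin, was at -1.64, the myosin light chain gene Mylpf at -1.16, the muscle regulator Myog at -1.93 and the acetylcholine receptor gene Chrna1, above the negative-control median on 1 array of each genotype, at -0.80. The muscle median was 0.03 without wild type replicate 2 (adjusted p = 0.798) and -0.20 without Foxn1 mutant replicate 3 (adjusted p = 0.318). It was -1.001 with the date code as a block, 0.61 within code A and -2.98 within code B. For both the neuron and the muscle list, 0 members passed when adjusted over the list alone.

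The remaining 31 lists were not called between Foxn1 mutants and wild type (lowest adjusted p = 0.247). The FOXN1-dependent list had a median of -0.06 with 6 of 13 members higher (adjusted p = 0.847), the T lineage list a median of -0.09 (adjusted p = 0.526) and the epithelial identity list a median of 0.03 (adjusted p = 0.872). The leukocyte and FOXN1-dependent lists were low on 1 array of each genotype, wild type replicate 1 and Foxn1 mutant replicate 2. The 24 measured neighbours of Foxn1 on chromosome 11 had a median of 0.001 (adjusted p = 0.957). The number of lists called was 16 without wild type replicate 1 and 16 with the date code as a block, and in both fits the FOXN1-dependent, T lineage and leukocyte lists were called lower in the Foxn1 mutants. None of these 3 calls held with an estimated correlation, which gave an adjusted p of 0.477 for each without wild type replicate 1 and of 0.420, 0.389 and 0.463 with the block. The FOXN1-dependent median was -0.64 without wild type replicate 1 (adjusted p = 0.00650; adjusted p = 0.477 with an estimated correlation) and -0.53 with the block (adjusted p = 0.00722; adjusted p = 0.420 with an estimated correlation). Without both arrays that stood apart it was -0.22 (adjusted p = 0.318). In that camera fit the T lineage median was -0.10 (adjusted p = 0.518) and the leukocyte median -0.085 (adjusted p = 0.288). The block and the fit without wild type replicate 1 are not separate evidence. Code C holds that array and no Foxn1 mutant, so the block lowers its weight here, while Foxn1 mutant replicate 2 stays in both fits. The Y-linked genes separated these genotypes completely, so a term for sex, chosen after the data had been seen, rests on Tbx1 mutant replicate 1 against Tbx1 mutant replicates 2 and 3, which also differ in date code. With it the median was -0.82 for the erythroid list (adjusted p = 0.0547), 0.34 for mesenchyme (adjusted p = 0.284) and -1.67 for neurons and glia (adjusted p = 0.171), and the loss of these calls cannot be assigned to sex.

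**Figure D2:**
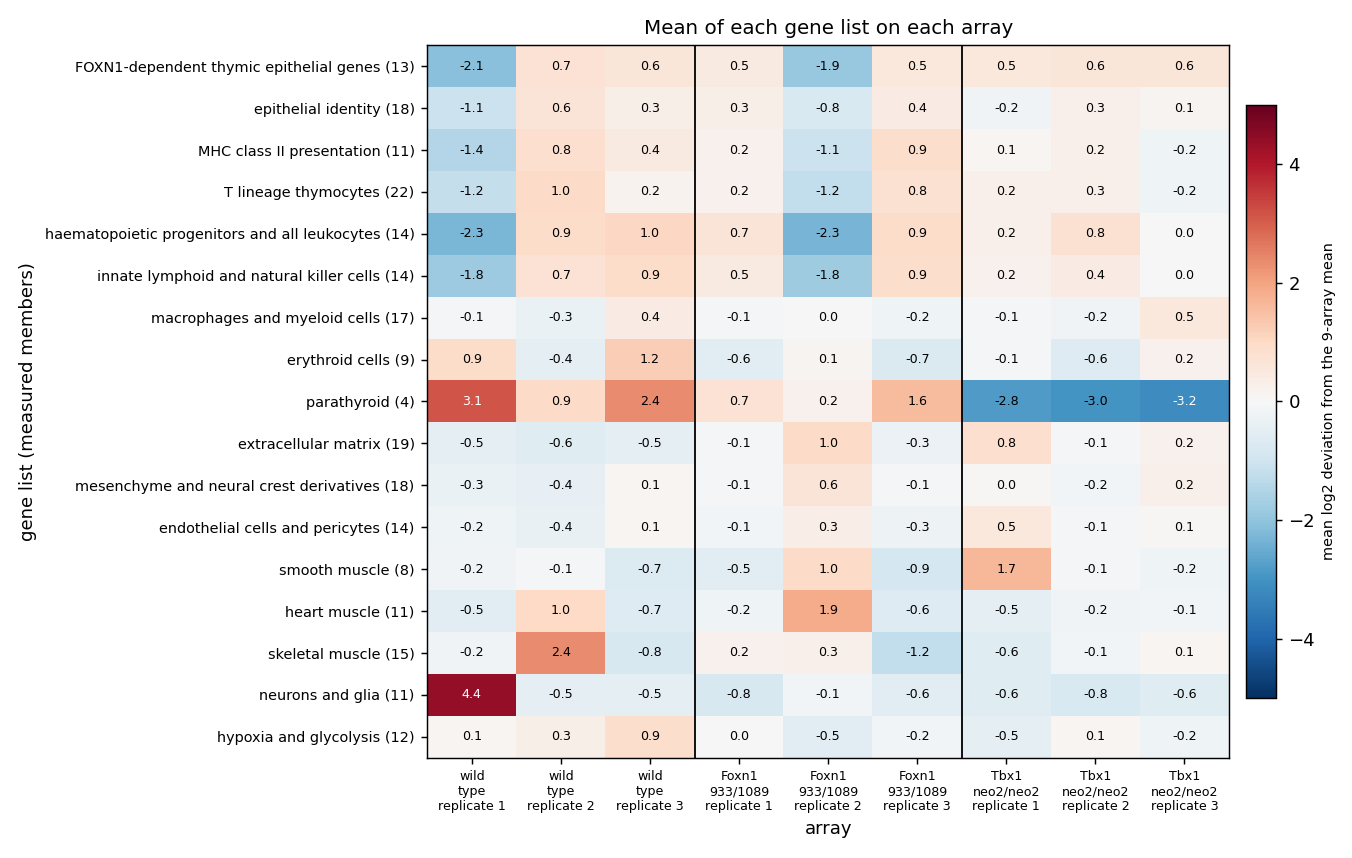
Mean log2 difference from the mean of all 9 arrays for 17 gene lists, 1 column per array; the colour scale runs from -5 to 5. The neuron and glia list stands out on wild type replicate 1, and the FOXN1-dependent and leukocyte lists are low on that array and on Foxn1 mutant replicate 2.

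The comparison of Tbx1 mutants with wild type asks which genes differ between the thymic lobe samples of these genotypes. Of the 4 measured parathyroid genes, Pth and Chga were called and fell in the Tbx1 mutants. Pth, the gene of parathyroid hormone, read 6.66 ± 0.52 in the Tbx1 mutants and 13.28 ± 1.22 in wild type (SD, n = 3), 98.6-fold lower. Chga, the secretory granule protein chromogranin A, read 4.30 ± 0.57 against 12.28 ± 1.61, at the level of the negative controls, so no fold is given. Casr, the calcium receptor through which parathyroid cells sense calcium, read 6.21 ± 0.73 against 11.96 ± 1.18 but was not called over all clusters (adjusted p = 0.107). Chgb was near background in both, and matrix genes as a list rose (adjusted p = 1.44e-10; adjusted p = 0.830 with an estimated correlation).

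With limma, 3 of 22206 clusters were called between Tbx1 mutants and wild type, and all 3 fell. The log2 change was -7.97 ± 0.69 for Chga (SE; adjusted p = 0.00892), -6.62 ± 0.58 for Pth (adjusted p = 0.00892) and -2.14 ± 0.23 for Cldn7, a tight junction claudin of epithelia (adjusted p = 0.0355). Chga was above the negative-control median on 1 of the 3 Tbx1 mutant arrays, so its value is only a bound: with that median as the lowest level of each array, the fall was at least 7.68. For each of the 3 genes, every Tbx1 mutant array lay under every wild type and Foxn1 mutant array. Of the 4 measured genes of the parathyroid list, which is too small for the set test, 2 were called over all clusters and 3 passed when adjusted over the list alone. Casr was at -5.75 ± 0.85 (adjusted p = 0.107) and Chgb at -0.20 ± 0.31. Within date codes A and C the differences were -6.77 and -7.67 for Pth, -9.00 and -9.03 for Chga, and -5.14 and -7.22 for Casr. With the date code as a block the log2 change of Pth was -6.89 (adjusted p = 0.0534) and that of Cldn7 -2.28 (adjusted p = 0.0534), and Chga alone was called. Pth and Chga were not called without wild type replicate 3 (adjusted p = 0.0597 for both), Tbx1 mutant replicate 2 (0.0633) or Tbx1 mutant replicate 3 (0.0984), when Pth was between -6.72 and -6.33 and Chga between -8.21 and -7.77. Cldn7 was not called when any 1 array other than wild type replicate 2 was left out (adjusted p up to 0.301), with its log2 change between -2.33 and -1.94. Without wild type replicate 2, 20 clusters were called, and without Tbx1 mutant replicate 1, 5 clusters. A term for sex read from Y-linked genes was chosen after the data had been seen. These genes were high on all wild type arrays and low on all Foxn1 mutant arrays, so the term compares 1 Tbx1 mutant array with 2 of another date code. With it, the comparison with wild type rests on Tbx1 mutant replicate 1 alone (Chga -8.60, Pth -6.22, Cldn7 -2.56). The 3 genes were then not called, which cannot be assigned to sex. A fit to the wild type and Tbx1 mutant arrays alone called 0 (adjusted p = 0.126 for Chga and Pth and 0.223 for Cldn7), and Cldn7 also lost its call after quantile normalization (adjusted p = 0.0667).

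**Figure D3:**
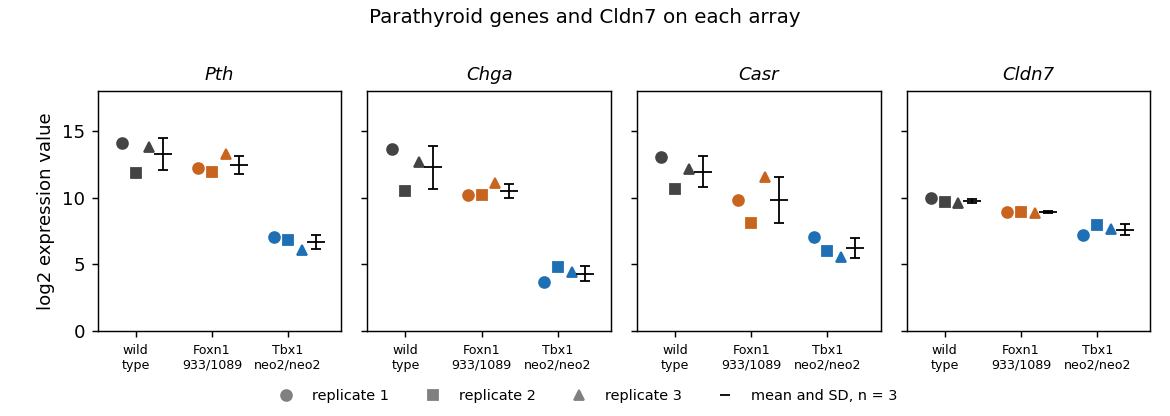
Log2 values of Pth, Chga, Casr and Cldn7 on each of the 9 arrays, with points for single arrays and bars for the mean and SD of each genotype (n = 3). Pth lies between 6.07 and 7.06 on the 3 Tbx1 mutant arrays and between 11.89 and 14.13 on the other 6.

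The Foxn1 mutants held Pth, Chga, Casr and Cldn7 at mean levels between those of the other genotypes, while Chgb was near background in all 3 (2.97 in the Foxn1 mutants, 3.49 in wild type, 3.28 in the Tbx1 mutants). Pth read 12.47 ± 0.69 (SD, n = 3), Chga 10.49 ± 0.53, Casr 9.85 ± 1.72 and Cldn7 8.91 ± 0.07 in the Foxn1 mutants. Their differences from wild type were -0.81, -1.78, -2.11 and -0.85, and none was called. Within code A these were -1.88, -2.51, -4.03 and -0.68, and within code B 0.845, 0.14, 0.02 and -0.80. Between Foxn1 mutants and wild type, 0 of the 4 parathyroid genes passed when adjusted over the list alone. Pth was 12.22, 11.95 and 13.25 on the Foxn1 mutants and 14.13, 11.89 and 13.83 in wild type.

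At an unadjusted p under 0.05 there were 841 clusters between Tbx1 mutants and wild type (437 higher, 404 lower), and the arrays did not overlap at 9.45% of clusters, where chance gives 10%. The genes next in line are given as values and not as changes. They were the ammonia transporter gene Rhcg (-3.25 ± 0.46, SE) and the G protein subunit gene Gng12 (-1.21 ± 0.17) on the lower side, each with an adjusted p of 0.107. On the higher side stood Mgp, an inhibitor of matrix calcification (2.66 ± 0.45), Dcn (1.56 ± 0.27), the myosin light chain kinase gene Mylk (1.94 ± 0.34), the sarcoglycan gene Sgcd (1.35 ± 0.24) and the olfactory receptor gene Olfr1034 (1.31 ± 0.23), which read under the negative-control medians on all 9 arrays. Rhcg was under them in the Tbx1 mutants (3.12), which limits how its difference can be read. The epithelial identity list, which holds Cldn7, was not called (adjusted p = 0.534). Its median of 0.04 and mean of 0.12 were positive while the test pointed down, and 9 of 18 members were higher. Adjusted over the list alone, Cldn7 was its 1 gene that passed; Plet1 was at -0.89, Epcam at -0.35 and Cldn6, under the negative controls in the Tbx1 mutants, at -0.48.

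The set test called 4 of 37 lists between Tbx1 mutants and wild type; none held with an estimated correlation (adjusted p = 0.830 for each). Fry called 0 in its directional form and 1, the medullary epithelium list, in its mixed form (adjusted p = 0.00373). That list holds the chemokine gene Ccl21a, at -3.76, and the mixed call does not show a change of medullary epithelium as a whole. The extracellular matrix list rose (adjusted p = 1.44e-10; adjusted p = 0.830 with an estimated correlation), with 17 of 19 members higher and a median of 0.80. Adjusted over the list alone, 3 members passed: Dcn, Col3a1 at 1.04 and Col1a1, the main collagen of connective tissue, at 1.43; Col1a2 was at 1.26. The matrix median was 0.73 with the date code as a block, 0.95 within code A and 0.70 within code C, and with any 1 array left out it was 0.52 to 0.95 (adjusted p at most 4.73e-06), the lowest without Tbx1 mutant replicate 1. The list mean was highest on Foxn1 mutant replicate 2 (11.29) and Tbx1 mutant replicate 1 (11.17).

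The other 3 called lists fell and moved with single arrays. The neuron and glia list (adjusted p = 5.33e-04; adjusted p = 0.830 with an estimated correlation) had a median of -1.39 with 10 of 11 members lower, and its mean was 10.36 on wild type replicate 1 alone (5.15 to 5.82 elsewhere). Dbh was at -3.39, the neuronal tubulin Tubb3 at -2.77, Nefm at -2.26 and the glial receptor gene Erbb3 at -1.06; Dbh was under the negative controls on all Tbx1 mutants. Without wild type replicate 1 its adjusted p was 0.358 with a median of -0.23. With the date code as a block the median was -2.59 (-0.05 within code A, -5.15 within code C, which holds wild type replicate 1). The skeletal muscle list (adjusted p = 0.00373; adjusted p = 0.830 with an estimated correlation) had all 15 members lower and a median of -0.61, with its high mean on wild type replicate 2 (8.04). Des was at -1.40, Acta1 at -1.49, Mylpf at -1.23 and the creatine kinase gene Ckm, under the negative controls in both genotypes, at -0.35. Its median was 0.02 without wild type replicate 2 (adjusted p = 0.818) and -0.53 without Tbx1 mutant replicate 1 (adjusted p = 0.0646), and with the date code as a block the median was -0.37 (adjusted p = 0.154; 0.12 within code A and -0.12 within code C). The hypoxia and glycolysis list (adjusted p = 0.00474; adjusted p = 0.830 with an estimated correlation) had 9 of 12 members lower and a median of -0.45, with Ndrg1 at -1.80, Adm at -1.89, Egln3 at -1.82 and the glucose transporter gene Slc2a1 at -0.70. With the date code as a block its median was -0.47 (adjusted p = 0.0735; -1.20 within code A and 0.18 within code C). Its median was -0.14 without wild type replicate 3 (adjusted p = 0.215), on which the list mean was highest (10.06), and -0.29 without Tbx1 mutant replicate 1 (adjusted p = 0.138). In these 3 lists 0 members passed when adjusted over the list alone.

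The other 33 lists were not called between Tbx1 mutants and wild type; the number called was 14 without wild type replicate 1, 7 without wild type replicate 3, 2 without Tbx1 mutant replicate 1 and 8 without Tbx1 mutant replicate 2. The smooth muscle list (median 0.65), the erythroid list (-0.33) and the FOXN1-dependent list (0.75) came closest, each with an adjusted p of 0.0513. The FOXN1-dependent median turned to -0.14 without wild type replicate 1 (adjusted p = 0.924), and it was 0.94 with the date code as a block (adjusted p = 1.58e-05; adjusted p = 0.743 with an estimated correlation). It was also called higher in 5 other fits, among them 0.97 without wild type replicate 3 (adjusted p = 0.0284; adjusted p = 0.932 with an estimated correlation). The smooth muscle mean was 7.40 on Tbx1 mutant replicate 1 and 4.86 to 6.70 elsewhere. The patterning factors of the pouch had a median of -0.07 (adjusted p = 0.524), and the 22 measured neighbours of Tbx1 on chromosome 16 a median of -0.03 (adjusted p = 0.940). Without the 2 arrays that stood apart, chosen after the data had been seen, Chga and Pth were still called and 15 lists were. The leukocyte list had no steady direction either: it was lower in the Tbx1 mutants in that fit (adjusted p = 8.16e-06; adjusted p = 0.422 with an estimated correlation) and higher with the date code as a block (adjusted p = 1.02e-04; adjusted p = 0.743 with an estimated correlation).

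The direct comparison of Foxn1 mutants with Tbx1 mutants asks how the mutants differ from each other. Pth was 56.2-fold higher in the Foxn1 mutants, and Chga, at background in the Tbx1 mutants, was higher too, but neither passed the test: Pth was at 5.81 ± 0.58 (SE, n = 3 per genotype; adjusted p = 0.0561) and Chga at 6.19 ± 0.69 (adjusted p = 0.0691), or at least 5.90 against the negative-control medians. Adjusted over the list alone, 3 of the 4 parathyroid genes passed. The FOXN1-dependent list was lower in the Foxn1 mutants (adjusted p = 0.0422; adjusted p = 0.969 with an estimated correlation), and it moved with Foxn1 mutant replicate 2, on which Prss16 was 4.45 and Psmb11 3.36.

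With limma, 0 of 22206 clusters were called between Foxn1 and Tbx1 mutants (lowest adjusted p = 0.0561), 661 had an unadjusted p under 0.05, and the arrays did not overlap at 8.92% of clusters, where chance gives 10%. Pth and Chga were called without wild type replicate 1 (adjusted p = 0.0166 for both; 3 clusters called), without wild type replicate 2 (adjusted p = 0.00211), with array weights (adjusted p = 0.00980; 4 clusters called), and without the 2 arrays that stood apart (adjusted p = 0.0420; left out together after the data had been seen). Other genes with the lowest p, given as values and not as changes, were Bpifa1, a secreted airway protein (2.26 ± 0.36, SE), Cldn7 (1.30 ± 0.23) and the fatty acid carrier gene Fabp4 (1.71 ± 0.32) on the higher side. On the lower side were the adhesion gene Parvb (-1.34 ± 0.23), the nucleotidase gene Entpd4 (-1.96 ± 0.37), Sgcd (-1.15 ± 0.24), Adam23 (-1.47 ± 0.34) and Cyp26b1, which degrades retinoic acid (-1.01 ± 0.23). Bpifa1 in the Tbx1 mutants (3.62) and Cyp26b1 in the Foxn1 mutants (3.72) were under the negative-control medians.

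Of 37 lists, 1 was called between the mutants; fry in its directional form called 0. The FOXN1-dependent list fell (adjusted p = 0.0422; adjusted p = 0.969 with an estimated correlation), with 11 of 13 members lower in the Foxn1 mutants and a median of -0.75. Among its members the chemokines Ccl25 and Cxcl12, which draw progenitors to the thymus, were at -0.54 and -0.75, Cd83 at -0.47 and Tbata at -1.49, and 0 passed when adjusted over the list alone. With the date code as a block the median was -1.59 (adjusted p = 1.27e-07; adjusted p = 0.459 with an estimated correlation), and within code A, the 1 code with both mutants, it was -1.54 between Foxn1 mutant replicate 2 and Tbx1 mutant replicate 1. The median was -0.12 without Foxn1 mutant replicate 2 (adjusted p = 0.608) and -0.44 without Tbx1 mutant replicate 1 (adjusted p = 0.146). The sex term gave the same values by construction, because it fits Tbx1 mutant replicate 1 exactly, so it is not a separate check. The median was -0.63 without Tbx1 mutant replicate 3 (adjusted p = 0.0556) and -0.12 without both arrays that stood apart (adjusted p = 0.701). After quantile normalization the adjusted p was 0.0532. The number of lists called was 4 without Foxn1 mutant replicate 1, 2 without replicate 2 and 8 without replicate 3, and 0 and 2 without Tbx1 mutant replicates 1 and 2.

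A test of any difference among the 3 genotypes called 2 clusters, Pth and Chga (adjusted p = 0.0189 for both), and 715 clusters had an unadjusted p under 0.05. With the date code as a block 1 cluster was called, and with the sex term 0. Leaving out wild type replicate 3, any 1 of the Foxn1 mutant arrays, or Tbx1 mutant replicate 2 or 3 gave 0 calls. Because both mutants were compared with the same 3 wild type arrays, their changes are related by construction. Across genes, which are not independent replicates, the log2 changes of the mutants correlated with r = 0.665, where 100 simulations of unchanged groups against shared wild type arrays gave 0.500 (SD 0.0148). The covariance was 0.113 against 0.092 in the simulations, and 69.6% of clusters changed in the same direction against 66.7%. Without the 2 arrays that stood apart r was 0.531, where simulations with those group sizes gave 0.549 (SD 0.0134). With any 1 array left out r lay between 0.558 and 0.801 and was each time above the simulations of its own group sizes (0.445 to 0.603), with 0.681 against 0.601 without wild type replicate 1 and 0.620 against 0.446 without Foxn1 mutant replicate 2. Of the fits compared, only the one without both of those arrays had an r not above its simulations. The simulations drew each gene independently and gave all arrays 1 spread. Wild type replicate 1 had an array weight of 0.339 and Foxn1 mutant replicate 2 of 0.462 (1.08 to 1.65 on the others). A more variable shared wild type array can raise r by itself, so an r above the simulations does not show a shared change. No gene was called in both mutants.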

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

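The settings that left out wild type replicate 1 and Foxn1 mutant replicate 2 together, left out X and Y clusters, added a term for sex or kept 1 cluster of each identical set were chosen after the data were seen. Across all settings, 1648 values of named genes kept direction and side of the threshold, 13 passed it newly, 21 no longer passed and 17 changed sign; for list medians these were 148, 0, 25 and 3. Except where stated, the cause was not tested. Over 12 settings fitted to all 3 genotypes with no single array left out, Chga was called in 11 in the Tbx1 mutants (adjusted p 0.00403 to 0.140), the size of its fall being limited by background; Pth was between -6.89 and -6.20 (called in 10; adjusted p 0.00403 to 0.285) and Cldn7 between -2.56 and -2.05 (called in 8; adjusted p 0.0259 to 0.140); none was called with the wild type and Tbx1 arrays alone (adjusted p 0.126, 0.126 and 0.223).

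Genes called are given in the order Foxn1 mutants against wild type, Tbx1 mutants against wild type, Foxn1 against Tbx1 mutants. An unadjusted p under 0.05 with at least 2-fold gave 164, 253 and 117 (247 for any difference). Only the arrays of the groups compared gave 1, 0 and 2, with fewer samples behind the spread. Array weights gave 17 for Tbx1 mutants against wild type and 4 for Foxn1 against Tbx1 mutants. An adjusted p under 0.1, and leaving out the 2 arrays that stood apart, each gave 2 for Foxn1 against Tbx1 mutants. For Tbx1 mutants against wild type, the date code as a fixed block gave 1, Chga (any difference: 1). With the sex term that comparison rests on Tbx1 mutant replicate 1 alone, and Pth, Chga and Cldn7 were not called (any difference: 0). The highest adjusted p of each of these genes over the 12 settings came from that term. Leaving out 1 array gave 0 to 3, 0 to 20 and 0 to 3 (any difference: 0 to 3).

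Lists called, in the same order, were 0, 0 and 0 with an estimated correlation and with fry in its directional form (the mixed form called 1 for Tbx1 mutants against wild type), 16, 9 and 14 with the date code as a fixed block, and 4 to 16, 2 to 14 and 0 to 8 with 1 array left out. For Tbx1 mutants against wild type they were 8 without clusters whose mean was under 5.15 and 15 without the 2 arrays, which gave 6 between the mutants.

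These values changed sign. Foxn1 in Tbx1 mutants against wild type was -0.30 with array weights, -0.64 without the 2 arrays and -0.49 with the sex term (-0.64 to 0.65 with 1 array left out); in Foxn1 mutants it ranged from -1.22 to 0.25 over all settings and from -1.04 with 1 left out. Tbx1 was -0.063 with the date code block in Tbx1 mutants against wild type and 0.021 between the mutants; with 1 array left out it ranged from -0.038 to 0.763, and from -0.70 to 0.10 in Foxn1 mutants. Chgb was 0.004 with array weights and 0.11 without the 2 arrays (-0.40 to 0.11 with 1 left out), and Alx1 was -0.055 with the sex term. Over all settings Chrna1 ranged from -1.64 to 0.026 in Foxn1 mutants and the muscle median from -1.27 to 0.026 (-1.22 to 0.021 in Tbx1 mutants), the upper ends being without wild type replicate 2. The mesenchyme median was -0.015 without the 2 arrays. The correlation of the mutants' changes was 0.531 without the 2 arrays (simulated 0.549) and 0.558 to 0.801 with 1 left out (simulated 0.445 to 0.603). Chga in the Tbx1 mutants and Tbx1 in every genotype lay near the negative controls, which limits how large a fall can be read there.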

Other observations

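The tests on date codes, sex and dissection behind the parathyroid genes, and on other tissue and genotype behind the arrays that stood apart, were chosen after those results had been seen, as were the genes named here; the tests on hybridisation, on X-linked genes and on other splits of the arrays were not.

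Chemokine genes of the Ccl21 family, which draw thymocyte progenitors and are made by medullary epithelium and by parathyroid, were low in the Tbx1 mutants. Their 7 clusters, some of which share identical values, differed from wild type by -4.60 to -3.76 with an adjusted p of 0.107 to 0.151, so none was called over all clusters. Ccl21b, Ccl21c and their near copies Gm10591 and Gm13304 were called with array weights, and these and Ccl21a without wild type replicate 2. The cluster of Ccl21a read 9.49 to 9.59 on the Tbx1 mutants, 11.05 to 12.84 on the Foxn1 mutants and 12.15 to 14.57 in wild type. In its mixed form, fry called the medullary epithelium list between Tbx1 mutants and wild type (adjusted p = 0.00373), while camera did not (adjusted p = 0.153). Adjusted over that list alone, 1 member passed, Ccl21a.

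Genes of other tissues varied from array to array within a genotype. Myh3, the embryonic myosin heavy chain, read 13.99 on wild type replicate 2 and 5.08 to 9.94 elsewhere. Prl8a2, a prolactin-family hormone, read 17.32 on that array and 4.43 to 13.56 elsewhere. Tpbpa, a trophoblast gene, read 12.28 on wild type replicate 1 and 3.12 to 10.56 elsewhere. A list of 13 placental trophoblast genes, written after the data had been seen, had a mean of 5.89 on wild type replicate 1, 5.08 on wild type replicate 2 and 3.94 to 4.88 elsewhere. Actg2, smooth muscle actin, read 7.75 on Tbx1 mutant replicate 1 and 3.00 to 6.47 elsewhere.

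Pth, Chga and Casr were low on all 3 Tbx1 mutant arrays. A difference between date codes is argued against by the falls within codes A and C, the smallest of which was -5.14. A difference in sex is argued against by the arrays with low Uty, among which the lowest Pth value of the Foxn1 mutants stood 5.10 above the highest of the Tbx1 mutants. The values do not show whether parathyroid tissue was missing. Pth and Casr were above the negative-control medians on all 3 Tbx1 mutant arrays, but the spread of the controls was not used, so this does not establish that they were detected. If it was missing, loss through the genotype and its omission from the dissected lobes both stay open. Either gives low values of all 3 genes. The smallest gap between the highest Tbx1 mutant array and the lowest other array was 1.11. The 3 genes were highest on wild type replicate 1 (14.13, 13.65 and 13.03). On that array the thymic epithelial and leukocyte lists were low, but Foxn1 read 7.78, above its negative-control median of 4.94. Without that array Pth was at -6.20 in the Tbx1 mutants, and Pth and Chga were still called.

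Thymic epithelial and leukocyte lists were low on wild type replicate 1 and Foxn1 mutant replicate 2. The 3401 bright clusters outside these lists had a median difference from the other 7 arrays of -0.288 and -0.101. The 14 bright members of the lists were at -4.41 and -3.30, so the fall was not common to bright clusters. The deposited values had background-probe medians of 4.727 on all arrays and cluster medians of 5.09 to 5.20. An even loss of signal may thus have been removed beforehand, and the test cannot exclude weak hybridisation. Wild type replicate 1 had the highest negative-control median (4.94) and the lowest positive-control median (9.90) of all arrays. These medians also leave a loss of signal on that array open. An effect of genotype shared by all arrays of a genotype is argued against by the nearer array of the same genotype, whose leukocyte mean was higher by 3.22 and 3.00. For wild type replicate 1, tissue other than thymic lobe may be a source of the signal, since 9 of the 11 neuron and glia genes were higher there than on all other arrays, with Nefm at 15.64, Tubb3 at 14.41, Chrna3 at 13.64 and Th at 12.44. For Foxn1 mutant replicate 2, 4 of 11 heart muscle genes were highest there, too few to decide. The tissue in that sample stays open, as do an effect of genotype that varies between samples and a mix-up with a sample from outside the series. Both tissue lists were picked after these arrays had been seen, so the counts cannot be set against chance.

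The Y-linked genes Uty and Kdm5d were low on the 3 Foxn1 mutant arrays and high in wild type. A difference in the sex of the embryos is a candidate explanation: of 4 X-linked genes known to escape inactivation, 3 were higher in the Foxn1 mutants and lowest, among the Tbx1 mutants, on replicate 1, the Tbx1 mutant array with high Uty (8.47). These were Kdm6a (1.10 higher), Eif2s3x (1.13) and Kdm5c (0.53), while Ddx3x (0.31 higher) was not lowest there. The labels give no sex, and in this comparison sex and genotype coincide. With a term for sex the number of genes called between Foxn1 mutants and wild type was 0. In the comparison of Tbx1 mutants with wild type the term leaves Tbx1 mutant replicate 1 alone, where Pth was at -6.22 and was not called. Without the term, a limma fit to the wild type and Tbx1 arrays alone gave Pth an adjusted p of 0.126. That term rests on 1 Tbx1 mutant array against 2 of another date code, so it does not separate sex from date code.

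Other splits of the arrays were counted for each test. For each pair of genotypes the 10 splits of 6 arrays are too few for a share under 0.05. Genes called in the real split were 0 between Foxn1 mutants and wild type, 3 between Tbx1 mutants and wild type and 0 between the mutants, and the highest other count was 0 in each (10, 1 and 10 splits as large, the real one included). Lists called were 6, 4 and 1, with 17 the highest other count in each and 8, 9 and 10 splits as large. In Foxn1 mutants against wild type, the 4 splits that place wild type replicate 1 and Foxn1 mutant replicate 2 together called 15 to 17 lists, which points to a structure of the arrays. The split with 17 also sets the 3 arrays of date code B against the rest. In Tbx1 mutants against wild type, the split with 17 follows no date code, and the split of date code C against the rest called 12 lists, as did 3 other splits. With the date code as a fixed block the real splits called 16 and 9 lists. For any difference, 100 of the 280 splits of all 9 arrays into 3 groups were counted, the real one included. Of these, 3 gave at least the 2 clusters called. The splits were a draw and ignored the date codes, so the share does not exclude chance. With the date code as a block 1 cluster was called, and with the sex term 0. The highest other count among the splits was 16, from a split that keeps the Tbx1 mutants together and sorts the other arrays differently. The cause of that count was not tested.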
